A study of Drosophila melanogaster with 12 samples.

How the data were processed

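RNA-seq libraries were made from adult Drosophila melanogaster heads after ribosome affinity purification. GFP-tagged ribosomal protein L10A was driven in neurons, glia or fat body, lysates of 1000 heads were prepared, and polyA RNA was sequenced from the lysate (Input) and from the material bound by the GFP antibody (IP). Per the labels, each biological replicate pools 4 technical replicates. The labels place the 12 samples in 6 groups of 2 replicates, named neuron, glia and fat body Input and IP, and all were kept.

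According to the submitters' processing notes, reads were aligned with TopHat2 2.0.6 to BDGP5, and transcripts were quantified and compared with Cufflinks 2.0.2 and Cuffdiff 2.0.2. The authors deposited 1 table of 15104 genes with 9 columns of values, and the FPKM of each of the 6 groups, deposited on a linear scale, had been combined by the authors over both replicates. The other 3 columns are the q-value that the authors gave to each gene for each pair of IP groups. How the replicates were combined, how the libraries were scaled to one another and which annotation release was used are not stated in the sources used here. The table carries neither counts nor values per replicate, so the depth and its precision are unknown and no confidence interval, standard deviation or test of differences could be computed. The analysis had been planned, before the data were examined, for the case of per-library values as well, with linear models and tests of gene sets. Those parts were not possible and were not run. The gene lists, the thresholds, the rule for naming genes and the alternatives were also set before the data were examined, except where stated otherwise.

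The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Genes with at least 1 FPKM in at least 1 group were analysed, 11181 in all. Log2 ratios are of FPKM plus a pseudocount of 1. For the 3 comparisons between IPs a gene counted as changed where the authors' q was under 0.05, and its direction was read from FPKM. Cuffdiff scales libraries internally, so the sign of a ratio and the test can rest on different scales. The 3 comparisons of IP with Input, the 3 between Inputs and the 3 differences of log2 IP/Input between cell types have no q, and there a gene counted from 2-fold upwards, leaving out genes listed at 0 in a compared group. A count adjusted over a list alone needs p-values per gene, which the table does not hold, so the counts given for lists use the q over all genes.

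Genes were named by rule. elav, repo, to and RpL10Ab were always named. In each comparison the 10 largest rises and 6 largest falls were taken among genes with at least 5 FPKM in a compared group and a symbol other than a CG or CR number, past the threshold where there is a q. From each list the 2 genes with the highest mean FPKM and 2 others with the largest change were added, and the text uses a selection of these.

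The 28 gene lists were written from general knowledge and from symbol families. They cover driver and tag genes, pan-neuronal genes, transmitter synthesis and transport, transmitter receptors, neuropeptides, phototransduction, glia, septate junctions, fat body, lipid synthesis and storage, immune effectors, muscle, hemocytes, cuticle and lens, eye pigment, cytosolic ribosomal proteins, translation factors, mitochondrial ribosomal proteins, noncoding RNAs, circadian genes, odorant-binding proteins, chemoreceptors, cytochrome P450, glutathione transferases, heat shock, proteasome, glycolysis and mitochondrially encoded genes. The last had 0 members in the table and gave no result, so total scaling left out ribosomal protein genes alone. A further 5 lists, for accessory gland, ejaculatory duct and bulb, testis, gut proteases and flight muscle, were written after the Inputs had been seen. Some genes are on more than 1 list, the largest overlap being the 6 genes shared by the glia and septate junction lists. For each list the median log2 value was compared with the medians of 10000 random lists of the same size drawn from the same 20 bins of mean FPKM, and a list stood apart in the lowest or the highest 2.5% of them. After the data had been seen, a version was added in which each random gene was drawn from the 100 genes nearest in mean FPKM and transcript length. Members of a list were not left out of either draw. This can bring the random median towards the list, most where the members are alike in level and length. Lengths came from a later annotation of the fly genome matched by gene identifier and were found for 10574 of the 11181 genes (94.6%). No coordinates were used.

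The procedure was tested on simulated data in which lists of 20 genes were changed 4-fold between the neuron IP and Input columns. The list statistic called 20 of 20 raised lists, 20 of 20 lowered lists and 10 of 200 unchanged lists (5%), or 13 with matching on length. Each simulated column was the neuron Input with independent noise per gene, and the unchanged lists were random draws. A rate near 5% follows from that construction and does not carry over to lists whose members vary together. Every member of the raised and lowered lists was changed, so the calls of 20 of 20 follow from it too. They do not show how often lists with only some changed members would be called.

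The alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, scaling of the columns to equal medians and to equal totals, a q threshold of 0.01, and q under 0.05 together with a log2 change of at least 1. Leaving out genes that were high in the glia Input and matching on transcript length were added after the data had been seen. A count was taken to have moved where it changed by more than 1.5-fold.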

Results

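RNA was sequenced from heads of adult flies in which 1 of 3 cell types carried a GFP-tagged ribosomal protein L10A. The tag was expressed under Elav-Gal4 in neurons, under repo-Gal4 in glia and under takeout-Gal4 in the fat body, the insect tissue of storage, secretion and humoral immunity. Ribosomes were pulled from the lysate of 1000 heads with an antibody against GFP, giving the IP libraries, and an aliquot of the same lysate gave the Input libraries. The 12 samples formed 6 groups of 2 biological replicates, an Input and an IP for each cell type. The values analysed here were 1 FPKM per gene and group, into which the authors had combined both replicates, so no value below has a standard deviation or an n, and no difference could be set against the spread between replicates. FPKM (fragments per kilobase of transcript, relative to all mapped fragments) carries no counts, so the depth behind each value is unknown. Of 15104 genes, 11181 reached 1 FPKM in at least 1 group. Log2 ratios are of FPKM plus 1.

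Over the 5599 genes with at least 5 FPKM in every group, the 3 Inputs were close to one another and the 3 IPs were not. Across these genes, which are not independent replicates, Spearman's rho was 0.976 to 0.986 between Inputs. It was 0.679 between neuron and glia IP, 0.712 between neuron and fat body IP and 0.790 between glia and fat body IP. Genes that were low in any group are left out of these values, among them genes that set the glia Input apart, described below. Nplp3, which encodes a neuropeptide-like precursor, had the highest FPKM in each Input (13821, 11374 and 11903 in the neuron, glia and fat body lysates) and in the neuron IP (20672). Arr2, the photoreceptor arrestin, came next in the neuron IP at 12717 FPKM. The glia IP was led by RpL10Ab at 21969 FPKM, CG7203 at 20582 and the metallothionein MtnA at 18654, an order that leaves out Nplp3, listed at 0 in that group with no statement of whether it was measured or missing. Nplp2, a haemolymph peptide precursor, led the fat body IP at 54996 FPKM, followed by CG6503 at 44633 and RpL10Ab at 44378, with Adh likewise listed at 0. Genes of cytosolic ribosomal proteins took 27.2%, 31.1% and 29.2% of the FPKM sum in the neuron, glia and fat body Inputs and 17.6%, 21.1% and 32.5% in the IPs. The FPKM sums themselves were 636575, 570917 and 578807 in the Inputs, 839267 in the neuron IP, 839886 in the glia IP and 1704813 in the fat body IP.

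The genes that name the drivers and the tag differed between the groups. repo (FBgn0011701), the homeodomain factor of glia, stood at 141 FPKM in the glia IP against 22.4 in its Input, 11.2 in the neuron IP and 20.9 in the fat body IP. takeout (to, FBgn0039298) had 44.4 FPKM in the fat body IP and 55.8 in the glia IP, against 9.57 in the neuron IP and 9.32 to 12.5 in the Inputs. elav (FBgn0260400), the RNA-binding protein of neurons, was lower in each IP than in its Input, at 3.48 against 15.0 FPKM for neurons, 1.36 against 5.97 for glia and 1.88 against 7.55 for the fat body. RpL10Ab (FBgn0036213), the gene of the tagged protein, had 7705, 21969 and 44378 FPKM in the neuron, glia and fat body IPs against 2083, 2353 and 2273 in the Inputs.

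**Figure D1:**
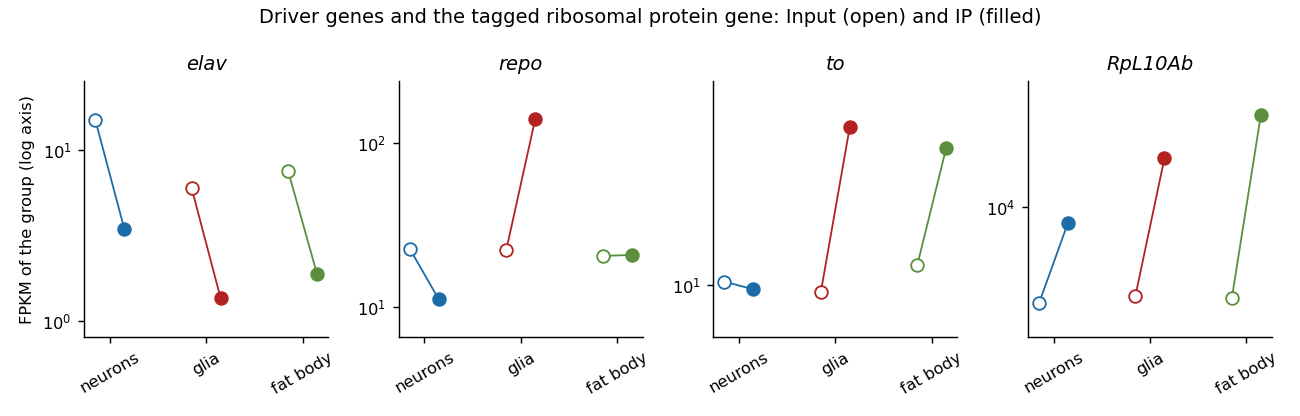
FPKM on a log axis of elav, repo, to and RpL10Ab, 1 panel per gene, with open points for Inputs, filled points for IPs and a line joining the Input and the IP of a cell type; each point is the authors' value for a group of 2 replicates. repo stood at 141 FPKM in the glia IP, and RpL10Ab between 7705 and 44378 FPKM in the IPs.

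The IP of each cell type was compared with its own Input to ask which transcripts were bound to tagged ribosomes more or less than their share of the head. These 3 comparisons have no test, and a gene counted as higher or lower from 2-fold upwards, leaving out genes listed at 0. The scale of the columns moved these counts. When each column was scaled so that the median log2 ratio to the mean of all columns was 0 over the 5599 genes with at least 5 FPKM in every group (median scaling), the log2 IP/Input of well expressed genes shifted down by 0.52 for neurons, 0.47 for glia and 0.80 for the fat body. When the columns were scaled to equal totals without ribosomal protein genes (total scaling), the shifts were 0.58, 0.75 and 1.49. The log2 values below are those of the deposited scale and are to be read relative to these shifts. The medians of gene lists are set beside the median of random lists of like mean expression, which carry the same shift. A list's percentile is its place among 10000 such lists, and a list stood apart when it lay in the lowest or the highest 2.5% of them.

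In the neuron IP most of the largest log2 values belonged to neuropeptide precursors. IFa, the precursor of IFamide, went from 50.5 FPKM in the Input to 1612 in the IP (log2 4.97). hug, which encodes the feeding-related hugin peptides, went from 17.9 to 376 FPKM (4.32), and capa, a diuretic peptide precursor, from 19.4 to 399 (4.30). Crz, npf and Dsk, the genes of corazonin, neuropeptide F and drosulfakinin, had log2 values of 3.73, 3.70 and 3.67, and Pdf, the transmitter of clock neurons, went from 39.2 to 471 FPKM (3.55). Tdc2 and Trh, the enzymes for octopamine and serotonin synthesis, were higher by 2.87 and 2.77, Gad1, the enzyme that makes GABA, by 0.61, and Arr2 by 1.74 (3807 to 12717 FPKM). The small heat shock gene Hsp23 was also higher (25.4 to 251 FPKM, log2 3.25). At the other end stood pAbp, the poly(A)-binding protein (387 to 12.2 FPKM, -4.88), the stress-response genes scyl (-4.32) and chrb (-4.19), Hrb27C, an hnRNP (-4.10), and Pdp1, a bZIP factor of the clock (-3.99). Several genes of neuronal function were lower too, among them cpx, the synaptic complexin (773 to 145 FPKM, -2.41), fne, a relative of elav (-3.73), and Sh, a potassium channel gene (-3.03), while n-syb, the neuronal synaptobrevin, stood at 396 FPKM in the Input and 332 in the IP (-0.25).

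Of the 27 neuropeptide genes 22 were at least 2-fold higher and 1 lower in the neuron IP, with a median log2 of 2.72 against 0.27 for random lists (percentile 100). Phototransduction genes had a median of 1.37 (13 of 20 higher, 3 lower, percentile 99.9), with ninaE, the major rhodopsin gene, at 0.53 (negative under total scaling) and rdgA and rdgB, a kinase and a lipid-transfer gene of photoreceptors, at -2.15 and -2.16. Mitochondrial ribosomal protein genes were higher as a list (median 1.71, 68 of 71 at least 2-fold), as were heat shock genes (1.09, 7 of 13). Chemoreceptor genes were higher by 0.83 (8 of 25, percentile 100), which no longer held among genes with at least 5 FPKM. The 35 pan-neuronal genes had a median of -1.94, with 24 at least 2-fold lower and 0 higher, against -0.03 for random lists (percentile 0) and -0.67 for random lists matched on transcript length as well (percentile 0). Genes of glia (-0.87, 14 of 30 lower), septate junctions (-0.71), the fat body (-0.82, 12 of 26 lower), lipid synthesis (-0.76), muscle (-0.84, 8 of 21 lower), hemocytes (-1.23, 7 of 9 lower) and noncoding RNAs (-0.63, 46 of 194 lower) also stood below their random lists. Among them, nrv2, a sodium pump subunit of glia, had -2.23, Yp1, a yolk protein gene of the fat body, went from 8749.8 to 2368 FPKM (-1.89), Rfabg, the lipophorin gene, had -2.94, and bt, which encodes a giant muscle protein, -3.07. Cytosolic ribosomal protein genes (-0.28) and circadian genes (-0.45) were below random lists of like expression but not below those matched on length. Ribosomal protein genes could themselves be drawn into the length-matched lists, so for them this does not show that length explains the median. Lists that did not stand apart were transmitter synthesis and transport (0.49, with the length-matched percentile at 98.8), transmitter receptors (-0.47), immune effectors (-0.21), cuticle and lens (0.02, negative under both scalings), eye pigment (0.80), translation factors (-0.23), odorant-binding proteins (-0.24), cytochrome P450 (-0.26), glutathione transferases (0.47), proteasome (0.31, negative under both scalings), glycolysis (0.84) and the 4 driver and tag genes (-0.53). With matching on length, immune effectors, odorant-binding proteins and cytochrome P450 lay under the 2.5th percentile (0.840, 0.755 and 0.01). Over all genes 2111 were at least 2-fold higher and 1457 lower (59.2% higher), with 39 listed at 0 left out. The share higher was 25.3% under median scaling (864 and 2550) and 22.0% under total scaling (788 and 2801).

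In the glia IP several genes of glia were higher than in the Input. wrapper, an immunoglobulin protein of midline and wrapping glia, went from 3.75 FPKM in the Input to 45.3 (log2 3.29), and Mdr65, a transporter of the blood-brain barrier, was higher by 2.88. nrv2 went from 183 to 489 FPKM (1.41), Gs2, the glutamine synthetase of glia, from 1033 to 2344 (1.18), and pck, a septate junction claudin, was higher by 1.71. The odorant-binding protein gene Obp44a went from 685 to 11168 FPKM (4.02), and dro4 and dro5, members of the drosomycin family, had 3.91 and 3.68. Genes of the male reproductive tract were also among the 10 highest, with Acp32CD, a seminal fluid protein gene, from 2.71 to 59.5 FPKM (4.03), Acp54A1 from 33.4 to 459 (3.74), Dup99B, a peptide gene of the ejaculatory duct, at 3.44 and Anp, the antibacterial andropin gene of the same duct, from 53.4 to 567 FPKM (3.38). The cuticle protein gene Acp1, which shares only its abbreviation with the seminal genes, went from 602 to 4353 FPKM (2.85), and Cpr49Ab had 3.32. At the low end stood several genes that were lower in the neuron IP than in its Input too. sif, a guanine nucleotide exchange factor of synapses, had -4.29, Cam, the calmodulin gene, went from 969 to 48.8 FPKM (-4.28), and Syt1, the calcium sensor of synaptic vesicles, from 51.5 to 3.51 (-3.54). Appl, the neuronal amyloid precursor homologue, had -3.38. In the neuron IP sif stood at 2.67 FPKM against 55.9 in the neuron Input, and Cam at 206 against 1873. Syt1 had 14.0 against 85.9 there and Appl 7.08 against 48.7, so these falls are not particular to the glia IP.

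Of 30 glia genes 18 were at least 2-fold higher and 2 lower (median 1.19 against 0.36 for random lists, percentile 99.99). Septate junction genes stood at 0.75 (7 of 18 higher, 0 lower, percentile 97.7), which no longer held among genes with at least 5 FPKM. Cuticle and lens genes were higher by 1.35 (32 of 50), odorant-binding protein genes by 1.10 (18 of 33, with 5 lower), cytochrome P450 genes by 0.92 (36 of 73, with 3 lower), glutathione transferase genes by 1.78 (13 of 21) and the driver and tag genes by 2.53. Examples were Cyp9f2 at 2.65, Cyp6d5 at 2.43, GstE10 at 3.23 and GstD1, an abundant detoxifying enzyme, at 2.59. Immune effectors as a list did not stand apart (0.07, negative under both scalings), with the bomanin IM1 at 2.87 and the stress peptide TotA at -2.38. Below random lists stood pan-neuronal genes (-2.47, 31 of 35 lower), transmitter synthesis (-1.37, 10 of 15), transmitter receptors (-1.21, 20 of 26), neuropeptides (-1.76, 22 of 27), phototransduction (-1.64, 19 of 20) and muscle (-1.81, 17 of 21). Fat body genes were lower as a list (-0.98, with 13 of 26 lower and 7 higher), Yp1 having -1.76 and Cat, the catalase gene, 2.83. Against lists matched on length, the mitochondrial ribosomal and immune lists lay under the 2.5th percentile (0.01 and 2.02). The percentiles of cytosolic ribosomal proteins (-0.19), translation factors (-0.16), noncoding RNAs (-0.65), circadian genes (-0.52) and hemocyte genes (-1.07) lay under 2.5, and with matching on length only the first of them still did. Other lists did not stand apart, namely lipid synthesis (-0.12), eye pigment (0.67, negative under total scaling), mitochondrial ribosomal proteins (0.62, negative under total scaling), chemoreceptors (-0.34), heat shock (-0.03), proteasome (0.44, negative under both scalings) and glycolysis (0.61, negative under total scaling). In all, 2075 genes were higher and 2188 lower (48.7% higher), with 32 listed at 0 left out, against 24.6% higher under median scaling (1103 and 3379) and 16.3% under total scaling (798 and 4093).

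In the fat body IP the highest log2 values included that of RpL10Ab (4.29). Obp99b, an odorant-binding protein gene of the male fat body, went from 239 FPKM in the Input to 6963 (log2 4.86), Npc2g, a sterol-binding protein gene, from 173 to 2820.2 (4.02), and its relative Npc2h had 3.84. PGRP-SC2, an amidase that degrades peptidoglycan, went from 5.63 to 118 FPKM (4.16), TotX, a stress peptide gene, had 3.82, and nimC3, a nimrod receptor gene, 3.86. GstE7, GstD5 and GstE9 stood at 4.16, 3.90 and 3.85. Lsd-1, which encodes the lipid droplet protein perilipin, went from 80.6 to 653 FPKM (3.00), desat1, a fatty acid desaturase, had 2.23, and AcCoAS, which makes acetyl-CoA, 2.54. CCHa2, a peptide hormone gene of the fat body, was higher by 2.28. Yp1 went from 8361 to 18284 FPKM (1.13) and Yp3 had 1.35, and both turned negative under total scaling. sif (-4.19), nrv3, a sodium pump subunit of neurons (-3.36), Syt1 (-3.09), Cam (-3.07), rdgA (-3.002) and IA-2, a dense-core vesicle protein gene (-2.99), had the lowest values. All of them were lower in the neuron IP than in its Input too, IA-2 at 12.6 against 132 FPKM and nrv3 at 13.6 against 104.

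Of 26 fat body genes 23 were at least 2-fold higher and 0 lower (median 1.67 against 1.08 for random lists, percentile 99.6). Lipid genes had 1.63 (16 of 21 higher, percentile 99.0), immune effectors 2.64 (25 of 31 higher, percentile 100) and glutathione transferases 2.55 (17 of 21 higher). Cytochrome P450 genes stood above random lists at 0.89 (35 of 73 higher, 0 lower), a median that turned negative under total scaling, with Cyp309a1 at 3.76. Mitochondrial ribosomal protein genes were at 1.65 (69 of 71 higher), no longer apart among lists matched on length. Cytosolic ribosomal protein genes, with 83 of 93 higher and a median of 1.56, stayed just inside the random lists (percentile 96.9). Pan-neuronal genes (-2.15, 33 of 35 lower), transmitter synthesis (-1.19), transmitter receptors (-1.18), neuropeptides (-1.18, 17 of 27 lower and 1 higher), phototransduction (-1.08, 12 of 20 lower) and muscle (-0.86, 8 of 21 lower) stood below. The glia list was at -0.21 (percentile 0.160, and 12.98 with matching on length), and septate junction (-0.30), hemocyte (-0.69) and circadian genes (-0.46) were likewise low only without matching on length. Glycolysis (1.80), translation factors (1.02, negative under total scaling), proteasome (0.90, negative under total scaling), driver and tag genes (0.89, negative under total scaling), eye pigment (0.22, negative under both scalings), noncoding RNAs (-0.14), cuticle (-0.12), odorant-binding proteins (-0.06), chemoreceptors (-0.23) and heat shock genes (-0.12) did not stand apart. The odorant-binding and heat shock lists had positive means beside their negative medians. With matching on length, glycolysis stood above the random lists (percentile 98.4) and cuticle and odorant-binding genes below (0.330 and 0.230). Over all genes 3056 were higher and 1133 lower (73.0% higher), with 36 listed at 0 left out, and the share higher was 31.3% under median scaling (1230 and 2706) and 8.81% under total scaling (467 and 4835).

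**Figure D2:**
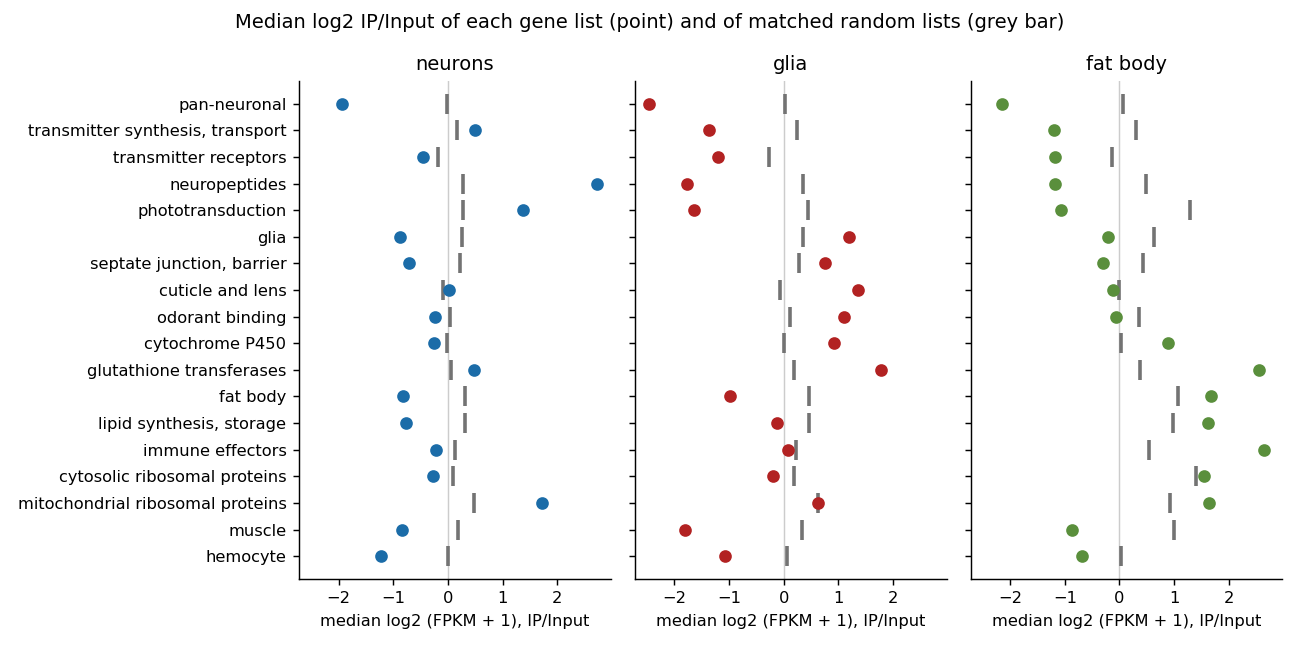
Median log2 IP/Input of 18 gene lists (points) in neurons, glia and fat body, 1 panel each, with grey bars at the median of random lists of like mean expression. Neuropeptides stood at 2.72 and pan-neuronal genes at -1.94 in neurons, glia genes at 1.19 in glia and immune effectors at 2.64 in the fat body, signs that both scalings kept.

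IP/Input was related to transcript length in each cell type. Over 5311 genes with at least 5 FPKM in every group and a known length, Spearman's rho across genes was -0.385 for neurons, -0.415 for glia and -0.481 for the fat body, and genes are not independent replicates. The median log2 IP/Input was 1.01, 0.97 and 1.45 for the 1202 genes under 1000 nt and -0.80, -0.50 and -0.51 for the 90 genes of 6000 nt or more. Between IPs the same correlation was 0.02 for neurons and glia, 0.11 for neurons and fat body and 0.14 for glia and fat body.

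The IPs were then compared with one another, which asks how ribosome-bound RNA differs between cell types without reference to the lysates. For these 3 comparisons the authors' deposited table gives a q-value per gene, and a gene rose or fell where that q was under 0.05, with the direction read from FPKM. Median scaling shifted log2 values by 0.30 between neuron and glia IP, by -0.13 between neuron and fat body IP and by -0.43 between glia and fat body IP, and total scaling by 0.06, -0.73 and -0.80, as amounts to be subtracted.

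Against the glia IP, the neuron IP was highest in neuropeptide genes. In the authors' deposited table the q was listed as 0 for IFa (log2 7.31), hug (6.03), Dms, the myosuppressin gene (5.98), capa (5.69), the insulin-like peptide gene Ilp2 (5.37), Pdf (5.33) and Mip, the gene of the allatostatin B peptides (5.28). Ilp5, another insulin-like peptide, had 260.4 against 6.94 FPKM (5.04, q 3.25e-05 in the authors' deposited table). Among genes of the synapse, Rab3, a vesicle GTPase, rose by 3.16 (q listed as 0), Snap25 by 3.10 (q 2.13e-14 in the authors' deposited table) and n-syb by 2.90 (q 1.49e-07). cpx had 1.91 but a deposited q of 1, a value that 228 genes shared in this comparison. The same value was given to 235 genes between neuron and fat body IP and to 186 between glia and fat body IP. The sources used here do not say whether such genes were tested. They are counted here among the genes that did not pass, which for them does not mean unchanged. Gad1 (3.87), Trh (4.82), Arr2 (3.90) and Rh4, a rhodopsin of colour vision (4.55), rose with q listed as 0, and ninaE rose by 1.62 (q 2.68e-05 in the authors' deposited table). repo fell (-3.54, q 3.98e-08 in the authors' deposited table), as did wrapper (-3.72), nrv2 (-3.25) and Gs2 (-1.33, q 0.00139). The lowest values were Anp (-7.23), Acp54A1 (-7.06), Dup99B (-6.30) and PebII, an ejaculatory bulb gene (-6.16), and the flight muscle actin Act88F also fell (-3.24, q 9.33e-09 in the authors' deposited table). For these 5 genes the Inputs already differed, by -0.83 (Dup99B) to -2.67 (Act88F). elav did not pass (3.48 against 1.36 FPKM, 0.92, q 0.320 in the authors' deposited table).

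Of 27 neuropeptide genes 26 rose and 1 did not pass (median 4.23), of 20 phototransduction genes 18 rose (3.32), and of 15 transmitter synthesis genes 10 (2.04). Pan-neuronal genes had 1.35 (19 rose, 0 fell, 16 did not pass) and transmitter receptors 1.36 (17, 0 and 9). Mitochondrial ribosomal proteins (1.43, 47 rose and 24 did not pass), chemoreceptors (1.27, 11 rose and 3 fell), heat shock genes (1.08, 7 rose and 6 did not pass) and muscle (0.86, 8 rose and 2 fell) were above random lists. Glia genes stood at -2.08 (21 fell, 1 rose, 8 did not pass), septate junction genes at -1.03 (5 fell), immune effectors at -1.14 (14 of 31 fell), cuticle at -1.51 (26 of 50 fell), odorant-binding proteins at -1.49 (20 of 33 fell), cytochrome P450 at -1.08 (31 of 73 fell) and glutathione transferases at -0.99 (9 of 21 fell). Fat body genes, which belong to neither cell type, were at -0.25 (6 fell and 2 rose). In all 1737 genes rose, 1710 fell and 7734 did not pass.

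Against the fat body IP, the neuron IP was again highest in neuropeptides, with IFa at 5.95, hug at 4.99, Dms at 4.80, npf at 4.49 and Ast-C, the allatostatin C gene, at 4.37, for each of which the q in the authors' deposited table was listed as 0. Tektin-C, a gene of sperm tails and cilia, rose by 4.94 (q 1.03e-11 in the authors' deposited table) and Hsp23 by 4.17, but for Tektin-C the Inputs already differed by 3.92. n-syb (2.11, q 0.000162), Snap25 (2.44, q 8.12e-10), Gad1 (3.08) and Arr2 (3.17) rose in the authors' deposited table, while ninaE did not pass (0.55, q 0.338). Among the largest falls were PGRP-SC2 at -5.97, Cyp309a1 at -5.10, TotX at -4.78, TotA at -4.59 and the metallothionein MtnD at -4.54 (q 1.26e-11 in the authors' deposited table). Yp1 (-2.95, q 3.56e-07 in the authors' deposited table), Rfabg (-4.31), Obp99b (-4.23), Lsd-1 (-3.79) and desat1 (-3.62) fell, and so did the driver gene to (-2.10, q 0.000209). RpL41 stood for the ribosomal proteins at -2.09 (q 6.39e-07 in the authors' deposited table). Ef1alpha48D, the main elongation factor gene, had -2.84 with a q of 1 in the authors' deposited table.

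By list, 25 of 27 neuropeptides rose (median 3.78; CCHa2 was the 1 that fell, named here after its value was seen), 16 of 20 phototransduction genes (2.43), 10 of 15 transmitter synthesis genes (2.04), 11 of 26 receptors (0.78), 9 of 35 pan-neuronal genes (0.68, 0 fell), 10 of 25 chemoreceptors (1.17) and 5 of 13 heat shock genes (0.67). Fat body genes had -2.99 (22 of 26 fell, 0 rose), lipid genes -2.17 (17 of 21), immune effectors -2.62 (22 of 31), cytosolic ribosomal proteins -1.87 (81 of 93), glutathione transferases -2.26 (13 of 21, with 2 that rose), cytochrome P450 -1.14 (29 of 73) and translation factors -0.89 (12 of 36). Hemocyte genes were lower (-0.96, 4 of 9 fell), which no longer held among genes with at least 5 FPKM. Glia genes, which belong to neither cell type, did not stand apart (-0.53, 5 of 30 fell, positive under total scaling). Over all genes 1042 rose, 1336 fell and 8803 did not pass.

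Between glia and fat body IP, repo (2.70), wrapper (3.41), Mdr65 (2.88), nrv2 (2.30) and Atpalpha, the sodium pump's catalytic subunit (1.70), were higher in glia with q listed as 0 in the authors' deposited table, and Gs2 rose by 0.87 (q 0.000935). Genes of the male tract had the largest values, with Anp at 6.05 (q 8.75e-15 in the authors' deposited table), Acp54A1 at 5.98, Mur18B, a mucin-like gene, at 5.70, the seminal fluid gene Sfp93F at 5.40 and PebII at 5.28. For all 5 the Inputs already differed, by 1.34 (Sfp93F) to 2.26 (Acp54A1). Acp1 (3.96) and Obp44a (3.75) rose as well. On the fat body side stood Cyp309a1 (-6.87), Npc2g (-6.27), Obp99b (-6.23), sPLA2, a secreted phospholipase (-5.81), TotA (-5.70), Lsd-1 (-4.50), Lsp2, a larval storage protein gene (-4.41), and RpL30 (-2.02). to did not pass (55.8 and 44.4 FPKM, 0.32, q 0.130 in the authors' deposited table), and neither did RpL10Ab (-1.01, q 0.181).

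Of 30 glia genes 21 rose and 2 fell (median 1.13), of 18 septate junction genes 17 rose (0.78), of 50 cuticle genes 27 (1.39) and of 33 odorant-binding protein genes 19, with 7 that fell (1.47). Fat body genes stood at -2.70 (21 of 26 fell, 3 rose), lipid genes at -1.69 (15 of 21 fell), immune effectors at -1.32 (19 of 31 fell), cytosolic ribosomal proteins at -1.71 (83 of 93 fell), mitochondrial ribosomal proteins at -1.08 (66 of 71 fell) and translation factors at -0.94 (25 of 36 fell). Neuronal lists, which belong to neither cell type, were also lower in the glia IP, at -0.80 for neuropeptides (14 of 27 fell), -0.52 for pan-neuronal genes (19 of 35 fell) and -0.74 for phototransduction (17 of 20 fell), the last inside its random lists and positive under total scaling. Glutathione transferases (-0.90, 12 of 21 fell) stood apart only without the minimum of 5 FPKM, and the proteasome list (-0.67, 26 of 40 fell) turned positive under total scaling. Cytochrome P450 genes went both ways (-0.23, 24 rose and 29 fell, positive under both scalings). Over all genes 1443 rose, 3538 fell and 6200 did not pass (29.0% of the called genes higher in glia), and under total scaling the same calls split into 2459 and 2522 (49.4%).

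Genes above both other IPs in the authors' deposited table numbered 902 for neurons, 832 for glia and 1099 for the fat body. With the direction read from rescaled columns they were 902, 837 and 1094 under median scaling and 902, 877 and 993 under total scaling. If the pairs of comparisons were independent, 162, 221 and 423 would be shared, but each pair shares an IP group, so part of the excess can come from that group alone. The neuron set held 25 neuropeptide, 16 phototransduction, 11 receptor, 9 transmitter synthesis and 9 pan-neuronal genes. The glia set held 19 glia and 5 septate junction genes, and the fat body set 21 fat body, 14 lipid, 17 immune and 80 cytosolic ribosomal protein genes. Against its own Input the neuron set had a median log2 of 1.15 with 85.1% of genes above 0, the glia set 1.88 with 91.8%, and the fat body set 2.10 with 96.3%, where all genes had medians of 0.00, 0.04 and 0.09. Under total scaling the shares were 71.3%, 87.8% and 81.4%. The sets were chosen for a high value in the IP that is also the numerator, so values above those of all genes are partly built in.

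The Inputs are lysates of whole heads from the 3 strains, and comparing them shows how far the starting material differed. There is no test here either, and median scaling shifted the log2 values by 0.25 between neuron and glia Input, 0.15 between neuron and fat body Input and -0.10 between glia and fat body Input, total scaling by 0.24, 0.18 and -0.06. Genes of the male tract and the gut were higher in the glia Input, and so were single genes of flight muscle, although the flight muscle list did not stand apart (0.26 for neuron over glia and 0.01 for glia over fat body). That list was mixed. Its weakly expressed members TpnC4 (3.19 FPKM against 0.15 and 0.23 in the neuron and fat body Inputs) and Glut3 (1.22 against 0.24 and 0.35) were higher in the glia Input. Tm1 (323 against 390 and 343), Mlp84B, Mf and salm were lower there than in both other Inputs. Sfp33A4, a seminal fluid protein gene, had 24.2 FPKM in the glia Input against 2.20 and 2.16 in the neuron and fat body Inputs. Act88F had 39.3 against 5.35 and 4.09, Mst84Db, a sperm tail gene, 80.6 against 12.3 and 18.7, and Jon65Aiii, a digestive protease gene, 11.7 against 1.29 and 2.52. fln, the flightin gene of flight muscle, had 18.3 FPKM against 2.96 and 2.62, and Dro, the antimicrobial drosocin gene, 203 against 56.0 and 29.2. The noncoding RNA CR40469 stood at 383 FPKM against 0.268 and 0.0955. In the neuron Input Tektin-C had 33.96 FPKM against 3.96 and 1.31, and Kmn1, a kinetochore gene, 11.3 against 1.46 and 1.64. elav was at 15.0 FPKM there against 5.97 and 7.55. w, the white gene of eye pigment transport, was low in the fat body Input, at 5.67 FPKM against 21.0 in the neuron and 16.7 in the glia Input. w is also the marker of P-element transgenes, and the strains carry different drivers, so these values need not be those of the eye gene alone. Bin1, a transcriptional cofactor gene, had 234 FPKM in the fat body Input against 22.2 and 32.0, and Arc1, an activity-regulated gene, 373 against 111 in the neuron Input and 330.0 in the glia Input.

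Pan-neuronal genes were higher in the neuron Input than in the glia Input (0.90, 9 of 35 at least 2-fold) and the fat body Input (0.47, 4 of 35), and lower in the glia than in the fat body Input (-0.35). Phototransduction genes had 0.52, 0.37 and -0.26 in the same order, and transmitter synthesis genes 0.68 and 0.38 for the neuron Input. Immune effectors were higher in the glia Input, with -0.76 for neuron over glia (9 of 31 lower) and 0.60 for glia over fat body (10 higher, 1 lower). Lists drawn up after these genes were seen gave, for neuron over glia Input, -2.05 for testis (25 of 28 at least 2-fold lower), -1.29 for the accessory gland (26 of 42), -1.46 for the ejaculatory duct and bulb and -1.11 for gut proteases (9 of 18), and for glia over fat body Input 1.74, 1.26, 1.21 and 0.85. Between neuron and fat body Input they were -0.36, -0.05, -0.21 and -0.17. With matching on length the gut list did not stand apart between glia and fat body Input (percentile 96.9). Cytosolic ribosomal protein genes differed little (-0.06, 0.01 and 0.07, of which the second turned negative under both scalings). Between neuron and glia Input 110 genes were at least 2-fold higher and 1140 lower (59 and 1424 under median scaling, 65 and 1478 under total scaling, 30 and 268 with a pseudocount of 5 FPKM). Between neuron and fat body Input 58 were higher and 47 lower (55.2% higher, and 40.8% and 39.1% under median and total scaling, with 42 and 61 genes and 43 and 67). Glia and fat body Input differed in 891 genes that were higher and 37 that were lower (194 and 16 with a pseudocount of 5 FPKM).

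Because the lysates differed, the log2 IP/Input of 1 cell type was subtracted from that of another, which asks for differences between IPs beyond those between Inputs. With 1 value per group the difference has no test. Median scaling shifted these values by 0.05 for neurons minus glia, -0.28 for neurons minus fat body and -0.33 for glia minus fat body, and total scaling by -0.18, -0.91 and -0.74. For neurons minus glia IFa stood at 6.82 and hug at 6.08, and Anp at -5.53, Acp54A1 at -5.65 and repo at -3.55 were on the glia side. For neurons minus fat body IFa had 5.93, hug 5.44 and npf 4.88, against -4.70 for Lsp2, -4.53 for Lsp1beta, another storage protein gene, and -4.44 for TotX. For glia minus fat body Anp had 4.57, Acp32CD 4.56, Obp44a 4.08 and wrapper 3.34, against -6.22 for Obp99b, -5.77 for TotA and -5.72 for Npc2g. elav was at -0.28 for neurons minus glia and at -0.27 for neurons minus fat body, positive in the second under total scaling.

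The list of pan-neuronal genes, lower in each IP than in its Input, was less so in neurons, by 0.57 relative to glia (percentile 99.6) and 0.27 relative to the fat body (percentile 99.8). Neuropeptides differed by 4.00 and 3.96 and phototransduction genes by 2.88 and 2.35. Glia genes were at -2.29 for neurons minus glia, 1.26 for glia minus fat body and -0.74 for neurons minus fat body, the last not apart among lists matched on length. Fat body genes had -3.004 for neurons minus fat body, -2.79 for glia minus fat body and -0.36 for neurons minus glia, and immune effectors -3.01, -1.89 and -0.56. Cytosolic ribosomal proteins stood at -1.84 and -1.77 against the fat body, and cuticle genes at -1.46 and 1.56 on the sides of glia. For neurons minus glia 1501 genes were at least 2-fold higher and 1803 lower (45.4% higher, and 57.1% under total scaling, with 2087 and 1569). For neurons minus fat body there were 1085 and 2047 (34.6%, 47.2% under median scaling with 1418 and 1589, 76.4% under total scaling with 3078 and 952). For glia minus fat body there were 1107 and 1701 (39.4%, 55.7% under median scaling with 1389 and 1105, 72.2% under total scaling with 1894 and 730).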

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

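Leaving out the 875 genes at least 2-fold higher in the glia Input than in both other Inputs, and matching random lists on transcript length, were chosen only after the data had been seen; the others were set before. With 1 value per group there was no replicate to leave out, no replicate block and no fit limited to the groups compared, so the alternatives of that kind that had been listed beforehand were not run. No paired analysis was possible because the values of the replicates were not used here singly, the authors having combined them. The depth of the libraries is unknown, so what it limits could not be given.

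Of the counts of genes under an alternative, 121 stayed within 1.5-fold of the main count and 41 did not. Part of the 121 was fixed in advance. Between IPs the call rests on the deposited q, and a pseudocount cannot change the sign of a ratio. Without a filter, genes under 1 FPKM in every group cannot reach 2-fold between 2 groups at a pseudocount of 1. Of the values of the genes that the naming rule gives, 5031 were counted as the same. With a q these kept their call and, if called, their direction, and with no q they moved by less than 1.5-fold. No pseudocount or scaling alters the q, so for values with a q a pseudocount could change nothing and a scaling only the sign. A further 716 moved by more, 19 no longer passed at a q of 0.01, and 15 that were past the q threshold or the 2-fold limit changed sign. Sign changes of values short of those limits were not counted apart. Of the lists' excesses over random lists, 1737 kept their side of the percentile limits and, where called, their direction. Of the rest, 66 lost a call, 51 gained one, 3 gained one on the other side of 0 and 3 that were called reversed.

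The scale of the columns mattered most for IP over Input. Under median scaling the genes higher and lower were 864 and 2550 for neurons, 1103 and 3379 for glia, and 1230 and 2706 for the fat body. Under total scaling they were 788 and 2801, 798 and 4093, and 467 and 4835. Between neuron and glia Input 59 genes were higher under median scaling and 65 under total scaling. For glia over fat body IP 2459 genes were higher under total scaling. For neurons minus fat body 3078 were higher and 952 lower under total scaling. For glia minus fat body 1105 were lower under median scaling, and 1894 higher and 730 lower under total scaling. A scaling multiplies a whole column, which moves its log2 values 1 way, less at low FPKM, and genes over the 2-fold limit, so its own construction gives the cause. The same holds for the values past the q threshold or the 2-fold limit that changed sign. In fat body IP over Input, total scaling gave -0.36 for Yp1, -0.14 for Yp3, -0.29 for ras, -0.078 for Ef1alpha48D, -0.46 for Ef2b and -0.13 for mRpL55. In glia over fat body IP it gave 0.067 for Arr2, 0.27 for IM3, 0.27 for crq, 0.37 for ras, 0.18 for mRpL55, 0.00032 for Cyp1, 0.097 for Hsp83 and 0.35 for DnaJ-1, and median scaling gave 0.0072 for ras. Values short of those limits changed sign too and are not all given. For example, Gs2 in fat body IP over Input went from 0.27 to -0.53 under median and -1.22 under total scaling.

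With a pseudocount of 0.1, 2640 genes were lower in the neuron IP than in its Input, 227 were higher in the neuron than the glia Input, 108 were higher and 122 lower in the neuron than the fat body Input, and 1512 were higher and 74 lower in the glia than the fat body Input. With a pseudocount of 5, 673, 769 and 448 genes were lower in the neuron, glia and fat body IP than in the Input. Between Inputs, that pseudocount left 30 genes higher and 268 lower for neuron over glia, 20 and 19 for neuron over fat body, and 194 and 16 for glia over fat body. For the differences it left 932 higher for neurons minus glia and 656 for neurons minus fat body. A larger pseudocount shrinks the ratios of weakly expressed genes, which is the cause by construction.

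Among genes with at least 5 FPKM, 562 were lower in the neuron than the glia Input and 528 higher in the glia than the fat body Input, since fewer genes were compared. At a q threshold of 0.01, 1124 genes were lower in the neuron than the glia IP. With a log2 change of at least 1 as well as q under 0.05, 1602 genes were lower in the glia than the fat body IP. Both are stricter calls on the same q-values. Leaving out the 875 genes moved none of the 6 counts tested by more than 1.5-fold.

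Matching on length brought the excess of the glia list in fat body IP over Input from -0.85 to -0.24 and ended its call. The 3 reversals were small excesses over random lists among genes with at least 5 FPKM. The chemoreceptor list between glia and fat body Input went from -0.33 to 0.058, the cytochrome P450 list in glia minus fat body from 0.25 to -0.029, and the glutathione transferase list there from -0.47 to 0.042. The cause of these reversals was not tested.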

Other observations

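The test for loss of long transcripts was set before its own result was seen, but the matching on length that it uses was added after the data had been seen. The tests for RNA not taken mainly from neurons, for transgene mRNA, for ribosomal protein mRNAs as a class, for carried-over abdomen, for more males and for driver activity in body tissues were chosen only after the results that they concern had been seen.

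A few abundant genes were listed at 0 in 1 group. Nplp3, which led the Inputs, was listed at 0 in the glia IP while its other values ran from 8300 to 20672 FPKM, and Adh, the alcohol dehydrogenase gene, was listed at 0 in the fat body IP with 6272 to 12630 FPKM elsewhere. The authors' deposited table gave a q of 1 to the comparisons of either gene with the group at 0, and the sources used here do not say whether these zeros are measured or missing values. The small nucleolar RNA genes snoRNA:Me18S-A1576 and snoRNA:Psi18S-1377c were listed at 0 in the neuron IP and snoRNA:Psi18S-920 in the glia IP. No fold against the group listed at 0 was given for these 5 genes, which were picked after their values had been seen.

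Pan-neuronal genes were lower in the neuron IP than in its Input, with a median log2 of -1.94. Loss of long transcripts was tested first, because IP/Input fell with length in each cell type and the list's median length was 5640 nt against 1699 nt over all genes. Among random lists matched on length as well as expression the pan-neuronal median stayed at percentile 0 of the 10000, with the random median at -0.67, which argues against length as the whole cause while leaving it part of the difference. A second candidate explanation, that the RNA did not come mainly from neurons, was tested on the difference of IP/Input between neurons and the other cell types. The lower of its length-matched percentiles was 99.35, on the side of neurons, so relative to matched lists these genes fell less in the neuron IP than in the other IPs. RNA of which only a part was neuronal could also give such a difference, so the test cannot decide whether it came mainly from neurons. The design gives no biological explanation that was tested.

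RpL10Ab was far higher in each IP than in its Input, at log2 1.89, 3.22 and 4.29, and exceeded the median of the 92 other cytosolic ribosomal protein genes by 2.16 in neurons, 3.42 in glia and 2.73 in the fat body. In the fat body the class itself was higher (median 1.56, 85 of the 92 above 0, and 0.75 and 0.07 under median and total scaling), but as the whole cause it is argued against, since RpL10Ab lay 1.83 above the next gene, RpLP0-like, and in glia it lay 1.31 above RpS15Ab. In neurons the gap to RpS10a was 0.74, under the limit of 1 used for the others, and the test there was changed after that gap had been seen to the median of the 92 genes, which was -0.28 (SD over genes 0.35, and -0.79 and -0.85 under median and total scaling), so the class did not lie higher. Transgene mRNA of the tagged cells being counted as the endogenous gene stays open, since the excess was what raised the question and no reads were examined. Between Inputs, where unequal transgene mRNA would also show, RpL10Ab lay at most 1.18 SD over genes from the median of the others, which decides nothing if the amounts were alike, and no biological explanation was tested.

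Genes of body tissues were higher in the glia Input than in the other Inputs, the most abundant members of the lists being Mst57Db of the accessory gland (848 FPKM against 218 and 208 in the neuron and fat body Inputs), Mst84Dc of the testis (95.99 against 18.1 and 22.0) and the gut protease alphaTry (21.9 against 4.01 and 5.51). More males among the heads is argued against by the male-specific RNAs roX1 (11.9 FPKM against 24.6 and 23.6 in the neuron and fat body Inputs) and roX2 (4.89 against 10.9 and 7.91), whose higher median log2 for glia over another Input was -0.76, although the spread between replicates is unknown. These are only 2 RNAs, and the Inputs come from different strains, so their level need not follow the share of males alone. For driver activity in the body tissues as the whole cause, the testis genes were tested. They were lower in the glia IP than in its Input (-1.58, and -2.03 and -2.30 under median and total scaling). The duct and bulb genes, a list of 7 drawn up after the data had been seen, were higher there by 3.204 (median). Only 3 of those 7 were not already among the largest changes. Both results bear on that IP and not on the level in the Input, so they decide nothing about the cause of the Input difference. Carried-over parts of the abdomen stay open. With the genes already seen left out, the accessory gland (33 genes), testis (25) and gut protease (17) lists lay above lists matched on expression against both other Inputs (lowest percentile 99.8). With matching on length only the testis list did, the lowest percentile being 93.8 for gut and 96.5 for accessory gland genes. Against the neuron Input the random median rose from -0.09 to 0.33 for gut and from -0.03 to 0.73 for accessory gland genes. The lists' own medians hardly moved (0.99 before and after, SD over genes 0.75, and 1.07 and 1.06, SD 0.58). Genes of these lists were not kept out of the random draws, which can raise the random median, so matching on length cannot decide here. The test had first included flight muscle and was narrowed once that list was seen not to stand apart from the fat body Input (0.01, percentile 74.3). Members of that list went both ways, so its median cannot exclude the thorax. Act88F (39.3 FPKM against 5.35 and 4.09 in the neuron and fat body Inputs), fln (18.3 against 2.96 and 2.62) and TpnC4 (3.19 against 0.15 and 0.23) were higher in the glia Input. Tm1 (323 against 390 and 343) was lower there. The thorax stays open too, and no biological explanation was tested.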
